A study of Mus musculus with 16 samples.

How the data were processed

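Gene expression was measured by RNA sequencing in 16 libraries of Iba1-EGFP-positive cells sorted from mouse retina, 4 each at day 0 without treatment and at days 2, 4 and 7 after optic nerve crush. Per the labels' protocols, cDNA was amplified from lysed cells and libraries were made with the Nextera XT kit, which does not mark the strand of the RNA. Groups and replicate numbers were taken from the labels. The sample titles carry a 6-digit code, and its first 4 digits, which put replicates 1 and 2 of every day in batch 1 and replicates 3 and 4 in batch 2, were used as the batch. That these digits are a period of work is a reading of the titles and not stated in the labels. The title prefix is F for day 2 replicates 3 and 4 and M for the others.

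The deposited table gives FPKM, fragments scaled by the length of the gene and the reads of the library, for 55385 genes, made by the authors from reads that were mapped with STAR 2.7.2b and counted per gene with featureCounts 1.6.1 on the genome build GRCm38.p6 (mm10), per the submitters' processing notes. How reads with several places in the genome and reads on overlapping genes were counted, and which reads were left out, is not given in the sources used here. The gene lengths that the authors divided by are in the table as deposited. In every library the FPKM multiplied by the length summed to the same total, and the values were whole multiples of a step of 0.01 read (tolerance of 0.02 steps), so the total reads of each library could be recovered, from 8647276 to 15708302. Between 46.9% and 63.4% of the values above 0 were whole reads (same tolerance), so the counts behind the table were in part fractions. The values are not counts and were tested as FPKM. A read in a gene of 1 kb was worth 0.0637 to 0.1156 FPKM, and a value of 0 in such a gene allows up to 0.191 to 0.347 FPKM (3 reads), a floor that covers counting error only, since amplified reads without molecular identifiers are not independent molecules. All 37 mitochondrial genes were listed at 0, so a value of 0 is described only as listed at 0, and no fold change is given against a group with all 4 libraries at 0. A gene at 0 in only some libraries of a group has the change of the fit, which depends on the pseudocount and is no bound.

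Genes with at least 1 FPKM in at least 4 libraries were tested, 14795 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), with all 16 libraries in a single fit, a mean per day and the batch as a covariate. Changes and medians are on this log2 scale, which understates the change of low genes. Tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. The 5 comparisons were days 2, 4 and 7 against day 0, day 4 against day 2 and day 7 against day 4, and an F test covered the 4 days together. Where a count of libraries is given for a gene, it is the number of later libraries above, or for lower genes below, all 4 earlier ones. Changes within each batch and a test of whether they differed came from a limma fit with an interaction of day and batch.

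The design, the groups, the tests, 29 gene lists and the rule for named genes were fixed before the data were examined. The lists described were study genes, homeostatic microglia, disease-associated microglia, cytokines and chemokines, NF-kB response, interferon response, cell cycle, complement, class I and class II antigen presentation, phagocytosis and lysosome, glycolysis, oxidative phosphorylation, cholesterol synthesis and efflux, immediate early and dissociation genes, and ribosomal proteins, and, for other cells that a retina sample can hold, rod, cone, bipolar, amacrine and horizontal, retinal ganglion, Mueller glia and astrocyte, endothelial and pericyte, monocyte, border-associated macrophage, neutrophil, T, NK and B cell, and erythrocyte genes. The sort on EGFP should remove most cells that do not use the Iba1 promoter. Iba1 is also expressed by other macrophages, so monocyte-derived and border-associated macrophages can pass the same gate. The 24 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over 120 tests, and again with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way. Of the 55 list calls, 7 held with the estimated correlation: cell cycle at day 2, cytokines at days 4 and 7 against day 0 and at day 4 against day 2, and interferon, disease-associated microglia and monocyte genes at day 7.

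The rule for named genes took the genes of the title's subject in every comparison against day 0, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 FPKM in the higher group and libraries that did not overlap (5 and 5 in the other comparisons), and up to 4 members per list, or 2 for lists of other cells. Unnamed gene models, mitochondrial genes and genes with a duplicated name were left out of the rises and falls. Glul, Lyve1 at day 4, Ccr2, Hba-a1 and the overlapping partner genes fall outside this rule and were named after their values were seen. A further list and some genes that the rule takes are not reported here. Exon overlaps of the genes called under the rule were computed from the exon positions in the deposited table on either strand. Of these, 31 genes shared exon bases with another listed gene, and 16 shared more than 10% with one. Nuclear copies of mitochondrial genes and parent genes of pseudogenes were found with BLAST 2.17.0 (E-value of 1e-10) against GENCODE vM21 transcripts of the same build, with a minimum identity of 90%.

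Alternatives covered the pseudocount, the filter on low values, rescaling with median-of-ratios factors, quantile normalisation, the batch term, the replicate number as a block, library weights, the prefix F libraries, each batch alone, only the groups compared, and each library left out in turn. A further 7 were chosen after seeing the data: limma voom on the recovered reads, the full 6-digit code as covariate, protein-coding genes only, values rescaled without nuclear copies of mitochondrial genes, the rod list or the bipolar and Mueller lists as covariate, and leaving out both day 0 replicate 1 and day 7 replicate 4. No sample was left out of the tests as reported, and the table held no further column of sample values. No library pair differed by as little as sampling noise.

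The tests were run on simulated data first, with 200 genes changed by known amounts. Of 50 genes changed by 1, 2, 3 and 4 on the log2 scale, 1, 18, 30 and 35 were called for day 2 against day 0, 0, 26, 30 and 45 for day 4, 1, 23, 30 and 44 for day 7, 4, 25, 30 and 37 for day 4 against day 2, and 5, 19, 32 and 39 for day 7 against day 4. Of 14595 unchanged genes, 3, 7, 7, 9 and 7 were called. The F test called 127 of 200 genes changed by 3, and the interaction test 65 of 200 changed by 4. Changes near 1 on the log2 scale were thus rarely called in these simulations. The changed genes were drawn from those with a fitted mean of at least 5 FPKM. The simulated noise was independent between genes, with 1 spread per gene for all days. The counts therefore do not measure the rates of missed or false calls in the real data. At day 4 against day 0, where more genes were called, smaller changes passed too, such as 0.93 for Atp6v0c. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.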

Results

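Retinal microglia were sampled before and after optic nerve crush, an injury that damages the axons of retinal ganglion cells where they leave the eye. The cells were taken by fluorescence-activated sorting from retinas of Iba1-EGFP mice, in which EGFP marks cells that use the promoter of Iba1 (Aif1), and their RNA was sequenced in bulk. The 4 groups were day 0 without treatment and days 2, 4 and 7 after the crush, with 4 libraries each and 16 in all. The title of the series names, among others, the receptor GPR84 and the cytokines TNF and IL-1α, and the design text describes 4 time points under injury. The mice were 15 weeks old at day 0, 13 at days 2 and 4, and 16 at day 7, so the effects of age and day cannot be separated except between days 2 and 4, which had the same age. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

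The reads recovered per library ranged from 8647276 (day 2 replicate 1) to 15708302 (day 4 replicate 4). Between 9315 genes (day 7 replicate 4) and 16522 genes (day 0 replicate 1) reached 1 FPKM, a level in fragments scaled by the length of the gene and the reads of the library. The number in each sample title placed replicates 1 and 2 of every day in one period (batch 1) and replicates 3 and 4 in another (batch 2). This batch entered every test. Nuclear copies of mitochondrial genes took 9.18 ± 5.89%, 9.69 ± 6.48%, 5.48 ± 1.65% and 14.28 ± 5.3% of the reads (SD, n = 4) at days 0, 2, 4 and 7, while all 37 mitochondrial genes were listed at 0 in every library. The copies with the most reads, Gm28437, Gm10925 and Gm28661, are 100% identical to mt-Co3, mt-Atp6 and mt-Co2 where they align. Their reads cannot be told apart from those of the mitochondrial genes, so these shares are no measure of transcription of the copies.

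RNA of other retinal cells was present in all libraries. Rod photoreceptor genes were abundant, with Gnat1, the rod transducin subunit, at 2409 ± 1819 FPKM at day 0 (SD, n = 4). Day 0 replicate 1 stood apart. It held 173 FPKM of Hba-a1, an adult globin of red blood cells that stayed at or under 1.42 FPKM in the other libraries, and it had the highest mean log2 values of the rod list (8.80), the cone list (7.03), the Mueller glia list (5.98) and the endothelial list (4.87). Day 0 replicates 1 and 2 had mean log2 values of 4.73 and 4.46 for the bipolar cell list, against 2.51 and 1.96 in replicates 3 and 4. Ccr2, a marker of blood monocytes, was at or under 0.18 FPKM in every library.

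The genes named in the title were followed first. Gpr84 (ENSMUSG00000063234.5, chromosome 15, 103308235 to 103310612 in GRCm38) encodes a receptor for medium-chain fatty acids and was at 27.2 ± 17.9 FPKM at day 0 (SD, n = 4). It was at 32.9 ± 10.3 FPKM at day 2, 127.6 ± 34.3 FPKM at day 4 and 55.5 ± 37.0 FPKM at day 7. It rose at day 4 by 2.39 ± 0.43 on the log2 scale (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00725), in 4 of 4 libraries, with changes of 3.04 within batch 1 and 1.75 within batch 2. Of the exon bases of Gpr84, 39.5% overlap the antisense gene Gm49482, which changed by 2.38 at day 4 (limma, adjusted p = 0.00677). The library kit does not mark strand, so reads of these genes cannot be told apart and the level of Gpr84 itself is uncertain. The Gpr84 changes at days 2 and 7 were 0.46 (limma, adjusted p = 0.8, 0 of 4 libraries above all of day 0) and 0.98 (adjusted p = 0.379, 2 of 4).

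Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) was at 0.0636 and 0.06 FPKM in day 0 replicates 1 and 2 and listed at 0 in replicates 3 and 4. It reached 41.4 ± 11.2 FPKM at day 4 (SD, n = 4), a rise of 5.32 ± 0.86 on the log2 scale (limma, adjusted p = 0.00429, 4 of 4 libraries), with 5.34 and 5.30 within batches 1 and 2. Il1a (ENSMUSG00000027399.1, chromosome 2, 129299610 to 129309972), which encodes IL-1α, ranged from 0 to 48.6 FPKM at day 0 and was at 225.1 ± 59.4 FPKM at day 4, a rise of 5.57 ± 1.15 (limma, adjusted p = 0.0127, 4 of 4 libraries; 5.97 and 5.16 within the batches). Of its exon bases, 11.2% overlap the antisense gene Gm14023. None of the 16 fits that left out a single library ended the day 4 call of these 3 genes. With the bipolar cell and Mueller glia lists as covariate, chosen after seeing the data, all 3 calls were lost (Gpr84 1.54, Tnf 5.89 and Il1a 6.22; limma, adjusted p = 0.325, 0.101 and 0.185). All 3 were also lost with batch 2 alone (1.75, 5.30 and 5.16; adjusted p = 0.282, 0.32 and 0.316), and that of Il1a with batch 1 alone and with limma voom (5.97 and 7.48; adjusted p = 0.0761 and 0.0636).

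At day 2, Tnf was at 6.09 FPKM in replicate 4 and at or under 0.164 FPKM in the others (change of 0.72, limma, adjusted p = 0.856, 2 of 4 libraries above all of day 0), and Il1a was at 45.4, 1.06, 88.7 and 90.3 FPKM (2.68, adjusted p = 0.448, 2 of 4). At day 7, Tnf was at 8.43, 2.27, 25.2 and 0 FPKM (2.37, limma, adjusted p = 0.278, 3 of 4), and Il1a at 73.7 ± 29.6 FPKM (3.89, adjusted p = 0.194, 3 of 4). Within batches 1 and 2 the day 2 changes were 0.71 and 0.20 for Gpr84, 0.02 and 1.41 for Tnf and 1.78 and 3.58 for Il1a, and those of day 7 were 0.81 and 1.14, 2.39 and 2.36, and 4.81 and 2.97.

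**Figure D1:**
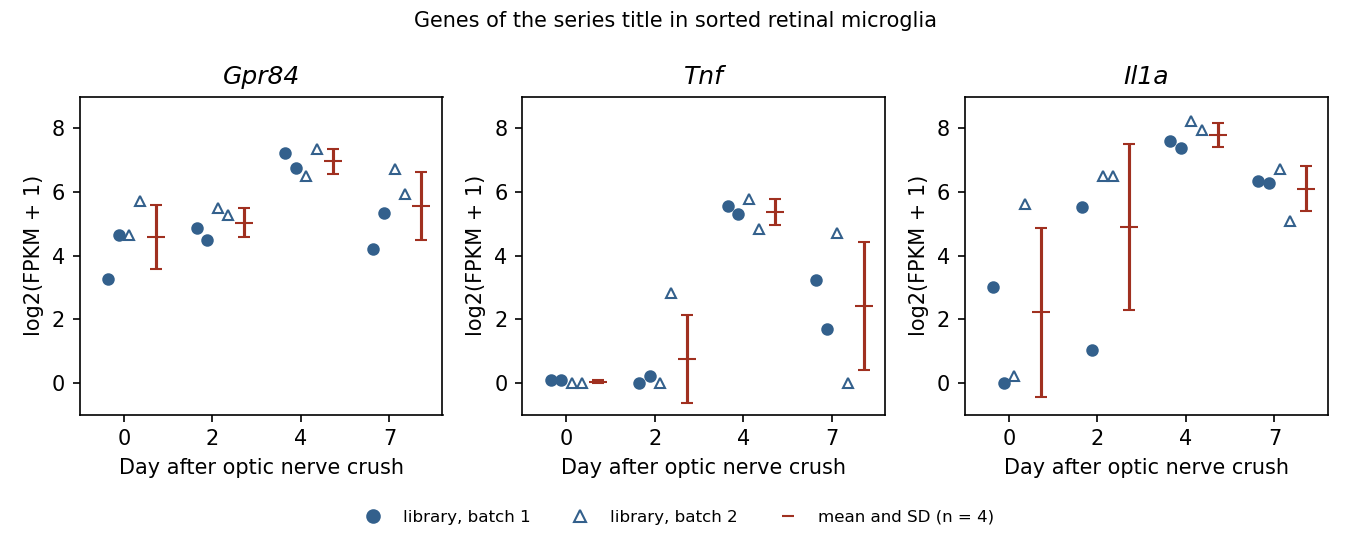
Levels of Gpr84, Tnf and Il1a as log2(FPKM + 1) on the vertical axis against the day after optic nerve crush on the horizontal axis, with 1 point per library, the symbol giving the batch, and a bar with whiskers for the group mean and SD (n = 4). All 4 day 4 libraries lie above all 4 day 0 libraries for each gene, with changes of 2.39, 5.32 and 5.57.

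The genes of C1q, the reporter, Rhoa and the ROCK kinases did not pass the test on any day against day 0. The complement genes C1qa, C1qb and C1qc, which encode the chains of C1q, had changes of 0.27, 0.37 and 0.53 at day 4 (limma, adjusted p = 0.588, 0.485 and 0.307, with 0 of 4 libraries above all of day 0 for each). At day 2 these were 0.35, 0.56 and 0.76 (adjusted p = 0.706, 0.535 and 0.356) and at day 7 they were 0.18, 0.28 and 0.52 (adjusted p = 0.817, 0.722 and 0.469). Aif1, the gene behind the reporter, had 0.56, 0.74 and 0.87 at days 2, 4 and 7 (adjusted p = 0.585, 0.183 and 0.265). Rhoa, the small GTPase that activates the ROCK kinases, had 0.35, 0.54 and −0.12 (adjusted p = 0.707, 0.23 and 0.888). Rock1 had −0.26, −1.01 and −1.14 (adjusted p = 0.906, 0.189 and 0.296) and Rock2 had −0.60, −1.42 and −2.15 (adjusted p = 0.828, 0.23 and 0.202). At day 4, 4 of 4 libraries lay above all of day 0 for Rhoa, and 4 of 4 lay below for Rock1. Rock2 was then at 2.49, 2.37, 4.91 and 0.00458 FPKM, against at least 4.03 FPKM at day 0. At day 7, 1 of 4 libraries lay above all of day 0 for Rhoa, and 4 of 4 lay below for Rock1 and for Rock2. At day 2, C1qc was at 3576, 2240, 3602 and 3700 FPKM, against at most 3180 FPKM at day 0. Limk1, a kinase downstream of ROCK, reached at most 1.73 FPKM and was not tested. Cfl1, the actin-severing cofilin, and Myl12a, a myosin regulatory light chain, rose at day 4, by 1.28 ± 0.24 and 0.96 ± 0.23 (limma, adjusted p = 0.00771 and 0.0273, 4 of 4 libraries each). Cfl1 changed by 1.72 and 0.84 and Myl12a by 1.28 and 0.65 within batches 1 and 2. Both calls were lost when the libraries were rescaled by median-of-ratios factors, that of Myl12a also when single libraries were left out, and both genes share exon bases with another gene (16.5% and 13.8%).

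The comparison of day 2 with day 0 addressed the early response to the injury. Genes of cell division rose. Ccnb2, the mitotic cyclin B2, was at 95.1 ± 17.9 FPKM at day 2 (SD, n = 4), against 0.193 FPKM in day 0 replicate 2 and 0 listed in the other day 0 libraries, a rise of 6.50 ± 0.80 (limma, adjusted p = 0.0031). Birc5 (survivin, needed for chromosome segregation), Spc24 (a kinetochore protein) and Nusap1 (a spindle protein) rose by 5.13 ± 0.67, 4.43 ± 0.51 and 4.16 ± 0.56 (adjusted p = 0.00487, 0.00265 and 0.00517). Stmn1, which destabilises microtubules, rose from 31.7 ± 15.3 to 382 ± 72.9 FPKM (3.67 ± 0.44, adjusted p = 0.00265). Each of these 5 genes was higher in 4 of 4 day 2 libraries and kept its call in all 16 fits that left out a library. None of the 5 was called without both libraries whose titles begin with F, or with batch 2 alone. The same held with the bipolar cell and Mueller glia lists as covariate, chosen after seeing the data.

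In all, 46 of 14795 genes changed between day 0 and day 2 (limma), 37 higher and 9 lower. Of the 40 tested cell cycle genes, 9 rose over all genes tested and 32 adjusted over the list alone, and none fell. The median change of the list was 2.80 (1.87 within batch 1 and 3.70 within batch 2; camera, adjusted p = 2.63e-33, and adjusted p = 0.0471 with an estimated correlation). Pbk, a mitotic kinase, rose by 6.43 ± 0.94 (limma, adjusted p = 0.00999), Ube2c, which tags mitotic cyclins for degradation, by 5.17 ± 0.94 (adjusted p = 0.0316), and the histone chaperone Asf1b by 4.39 ± 0.86 (adjusted p = 0.0483), in 4 of 4 libraries each. Leaving out a library ended these calls in 1, 7 and 13 of the 16 fits. The histone genes Hist1h2ao and Hist1h2ap had 4.48 and 4.45 (adjusted p = 0.0147 and 0.0148), but they are near-identical and each overlaps an antisense microRNA gene, so their values are uncertain. Outside the cell cycle, the interferon-induced gene Slfn2, a regulator of immune cell quiescence, rose by 3.94 ± 0.66 (adjusted p = 0.0163; 2.89 and 4.99 within the batches, 4 of 4 libraries). It was the only called member of the 29 tested interferon genes (4 adjusted over the list alone; median of 0.71; camera, adjusted p = 0.000167, and adjusted p = 0.233 with an estimated correlation).

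Among the 9 genes lower at day 2, Syn1, the synaptic vesicle protein synapsin, fell from 14.4 ± 4.21 to 0.0965 ± 0.0228 FPKM (−3.77 ± 0.68, limma, adjusted p = 0.0299) in 4 of 4 libraries. Zdhhc14, Zfp740, Aatk and Bicdl1 changed by −3.49, −3.62, −2.54 and −2.21 (adjusted p = 0.013, 0.0448, 0.0316 and 0.0483), in 4 of 4 libraries each. Of the 16 fits that left out a library, 7 ended the call of Syn1, 2 that of Zdhhc14, 11 that of Zfp740, 10 that of Aatk and all 16 that of Bicdl1. Mir7666 was at 13.4 ± 3.58 FPKM at day 0 and listed at 0 in all day 2 libraries (adjusted p = 0.0495), but it lies within an exon of Micu3 on the opposite strand and its reads are uncertain, and 13 of the fits ended its call. Lists of bipolar cells and Mueller glia also had negative medians. Of 10 bipolar cell genes none was called and 3 fell adjusted over the list alone. The median was −2.10 over the list, with −2.63 and −1.51 within the batches (camera, adjusted p = 7.5e-06, and adjusted p = 0.0578 with an estimated correlation). Of 12 Mueller glia and astrocyte genes none was called and 6 fell adjusted over the list alone. The median was −1.89 over the list, with −3.09 and −0.31 within the batches (camera, adjusted p = 8.07e-05, and adjusted p = 0.321 with an estimated correlation). Of 22 immediate early and dissociation genes, some of which respond to the handling of cells, none was called and 0 adjusted over the list alone. The median was −0.54 over the list, with −2.09 and 0.29 within the batches, of opposite sign (camera, adjusted p = 0.00167, and adjusted p = 0.457 with an estimated correlation). Of 17 glycolysis genes none was called and 0 adjusted over the list alone. The median was −0.71 over the list, with −0.50 and −0.52 within the batches (camera, adjusted p = 9.44e-05, and adjusted p = 0.347 with an estimated correlation). The oxidative phosphorylation and phagocytosis lists had medians of 0.38 and 0.36 with none called (camera, adjusted p = 0.000251 and 0.000327, and adjusted p = 0.365 and 0.457 with an estimated correlation; 0 and 1 higher adjusted over the list alone).

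The day 2 counts rested on few libraries and on the covariates. With the bipolar cell and Mueller glia lists as covariate, chosen after seeing the data, 0 genes were called (limma, 1105 at an unadjusted p under 0.05), and with the full 6-digit title code 126 were called, 40 of them among the 46. With median-of-ratios factors 37 genes were higher and 16 lower, a share of 69.8% higher against 80.4% before. The count was 18 without day 0 replicate 2, 77 without day 0 replicate 3, 17, 23, 11 and 8 without day 2 replicates 1, 2, 3 and 4, and 1 without both libraries whose titles begin with F (day 2 replicates 3 and 4). Of the 18 genes called at day 2 under the naming rule, 13 lost the call in at least 1 of the 16 fits, with a highest adjusted p of 0.181. The fits without day 0 replicates 1 to 4 lost 7, 9, 3 and 6 of them, those without day 2 replicates 1 to 4 lost 10, 9, 12 and 13, those without day 4 replicates 3, 5, 2 and 4, and those without day 7 replicates 4, 5, 2 and 2.

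The comparison of day 4 with day 0 gave 790 changed genes (limma), with 684 higher and 106 lower. With the bipolar cell and Mueller glia lists as covariate, chosen after seeing the data, 37 were called, 28 of them among the 790, and with the full 6-digit title code 379, of which 275. Genes of inflammatory mediators rose. Ccl12, a chemokine that attracts monocytes, rose from 317 ± 172 to 8024 ± 3579 FPKM (SD, n = 4), by 4.86 ± 0.43 (adjusted p = 0.000136; 4.91 and 4.81 within batches 1 and 2). The chemokines Ccl4 and Ccl3 rose from 40.2 ± 21.2 to 1011 ± 416 FPKM and from 35.3 ± 26.3 to 459 ± 171 FPKM (4.69 ± 0.65 and 3.95 ± 0.60, adjusted p = 0.00177 and 0.00342). Ccl2 and the interferon-induced Cxcl10 rose by 5.50 ± 0.85 and 5.05 ± 0.93 (adjusted p = 0.0035 and 0.0076). Il1b, which encodes IL-1β, was listed at 0 in all day 0 libraries and was at 57.0 ± 39.5 FPKM at day 4 (adjusted p = 0.00654). All of these were higher in 4 of 4 libraries.

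Of 17 tested cytokine and chemokine genes, 8 rose over all genes tested and 13 adjusted over the list alone, and none fell. The median change was 3.47 (3.65 and 3.29 within the batches; camera, adjusted p = 1.35e-10, and adjusted p = 0.00121 with an estimated correlation). Of 28 disease-associated microglia genes, 9 rose and none fell over all genes tested, with 12 higher and 1 lower adjusted over the list alone. The median was 0.96 over the list, with 1.16 and 0.52 within the batches and 0.54 with median-of-ratios factors (camera, adjusted p = 0.000112, and adjusted p = 0.256 with an estimated correlation). Among them were the lipoprotein lipase Lpl (4.44 ± 0.74, limma, adjusted p = 0.00506), Lgals3 (galectin-3, 5.05 ± 0.95, adjusted p = 0.00838) and the tetraspanin Cd63 (1.39 ± 0.24, adjusted p = 0.00511), each in 4 of 4 libraries. Lilrb4a, an inhibitory receptor, had 3.54 (adjusted p = 0.00355), but 35.3% of its exon bases belong also to Gm49339. Of 29 interferon genes, 8 rose over all genes tested and 12 adjusted over the list alone. The median was 1.44 over the list, with 1.48 and 0.96 within the batches (camera, adjusted p = 8.62e-05, and adjusted p = 0.228 with an estimated correlation). The 8 included Slfn2 (4.73, limma, adjusted p = 0.00177), Ifi204, a DNA sensor (2.28, adjusted p = 0.0082), and Oas1a, a sensor of double-stranded RNA (3.72, adjusted p = 0.0109), in 4 of 4 libraries each.

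Cell cycle genes were also high at day 4. Of 40, 15 rose over all genes tested and 30 adjusted over the list alone. The median was 2.73 over the list, with 3.51 and 2.05 within the batches (camera, adjusted p = 1.36e-16, and adjusted p = 0.172 with an estimated correlation). Nusap1, Birc5, Tyms (thymidylate synthase) and Stmn1 rose by 4.28, 4.44, 3.26 and 2.59 (limma, adjusted p = 0.00141, 0.00338, 0.00508 and 0.00511) and Pbk by 5.30 (adjusted p = 0.00658), in 4 of 4 libraries each. Genes of oxidative phosphorylation followed, with 6 of 30 higher over all genes tested and 17 adjusted over the list alone. The median was 0.73 over the list, with 0.66 and 0.68 within the batches, and 0.27 with median-of-ratios factors (camera, adjusted p = 6.6e-07, and adjusted p = 0.233 with an estimated correlation). Atp5g1, a subunit of ATP synthase, Cycs (cytochrome c), Sdhb (succinate dehydrogenase) and Cox5a (a subunit of cytochrome c oxidase) rose by 1.5, 1.70, 1.91 and 1.30 (limma, adjusted p = 0.00511, 0.0063, 0.0142 and 0.012), in 4 of 4 libraries each. Of the exon bases of Cox5a, 12.8% overlap the antisense gene Gm26631, which changed by 1.3 (limma, adjusted p = 0.0136). Of 30 ribosomal protein genes, 5 rose, among them Rpl6, Rps2 and Rpl27 (1.24, 1.29 and 1.33, limma, adjusted p = 0.0101, 0.0115 and 0.0256), and 11 adjusted over the list alone (camera, adjusted p = 1.48e-06, and adjusted p = 0.545 with an estimated correlation). Their median of 0.56 (0.83 and 0.38 within the batches) was 0.09 with median-of-ratios factors.

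Of 34 phagocytosis and lysosome genes, 6 rose and 1 fell over all genes tested, with 7 higher and 1 lower adjusted over the list alone. The median was 0.46 over the list, and 0.04 with median-of-ratios factors (camera, adjusted p = 0.0167, and adjusted p = 0.592 with an estimated correlation). The protease Ctsc and the Fc receptor Fcgr1 rose by 1.75 and 1.97 (limma, adjusted p = 0.00742 and 0.0076), and Psap, the precursor of the saposins, fell from 250.8 ± 95.7 to 88.8 ± 21.1 FPKM (−1.43 ± 0.31, adjusted p = 0.0156), in 4 of 4 libraries each. The proton pump subunit Atp6v0c had 0.93 (adjusted p = 0.0162, 4 of 4). Of 24 homeostatic microglia genes, 1 rose, the Fc receptor-like gene Fcrls (1.67 ± 0.35, limma, adjusted p = 0.0137, 4 of 4 libraries). The list had a median of −0.35, with 0.20 and −0.85 within the batches and so of opposite sign, and −0.81 with median-of-ratios factors (camera, adjusted p = 0.0152, and adjusted p = 0.592 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone). Of 16 class I antigen presentation genes, Psme2 and Psme1, activators of the proteasome, rose by 1.79 and 1.39 (adjusted p = 0.00405 and 0.0184, 4 of 4 each; 2 adjusted over the list alone). The list's median of 0.23 was −0.07 with median-of-ratios factors (camera, adjusted p = 0.362). Of 12 complement genes, the receptor C5ar1 had 1.70 (limma, adjusted p = 0.0373), in 3 of 4 libraries (1 higher and 1 lower over all genes tested; 1 higher and 1 lower adjusted over the list alone; median of 0.27, and −0.05 with median-of-ratios factors; camera, adjusted p = 0.844). Of 18 NF-kB genes, Bcl2a1b had 2.2 (limma, adjusted p = 0.0147, 4 of 4), but 49.1% of its exon bases belong also to Gm29094 (1 adjusted over the list alone; median of 0.73; camera, adjusted p = 0.248).

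No member was called at day 4 in the lists of class II antigen presentation (10 genes, median of 0.73; camera, adjusted p = 0.605; 0 adjusted over the list alone) and glycolysis (17 genes, −0.07, adjusted p = 0.681; 2 higher and 1 lower adjusted over the list alone). None was called either in the lists of cholesterol synthesis and efflux (21 genes, −0.02 with a mean of 0.02; camera, adjusted p = 0.482; 0 adjusted over the list alone) and immediate early and dissociation genes (22 genes, 0.38, adjusted p = 0.407; 0 adjusted over the list alone). The 7 study genes, chosen here from the title and from common microglia genes, had 3 called members and 3 adjusted over the list alone. The median was 0.74 over the list (camera, adjusted p = 0.000427, and adjusted p = 0.233 with an estimated correlation). With median-of-ratios factors the medians were 0.27 for study genes, 0.32 for NF-kB genes, 0.27 for class II genes, −0.52 for glycolysis, −0.40 for cholesterol genes and 0.08 for immediate early genes. A list that takes its genes from the title of the same study is not independent evidence of their direction.

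The 106 lower genes at day 4 included Id3, a transcription inhibitor, which was at 53.7 ± 47.0 FPKM at day 0 (SD, n = 4) and at 0.0239 FPKM in day 4 replicate 1 and listed at 0 in the other day 4 libraries (−5.25 ± 0.84, limma, adjusted p = 0.00429). Gpm6a, a membrane glycoprotein of neurons, was at 123 ± 118 FPKM at day 0 and at 7.90, 11.8, 0 and 0.099 FPKM at day 4 (−4.47 ± 0.51, adjusted p = 0.000473; −4.35 and −4.60 within the batches). Cend1, a gene of neuronal differentiation, and Ctu1, a tRNA-modifying enzyme, were at 18.9 ± 9.65 and 12.8 ± 3.72 FPKM at day 0 and listed at 0 in all day 4 libraries (adjusted p = 0.00342 and 0.00511). Arxes2, the glutathione transferase Gstt1 and Tcim had −4.61, −4.01 and −3.94 (adjusted p = 0.0097, 0.0111 and 0.00894). All were lower in 4 of 4 libraries. Of the exon bases of Tcim, 18.7% overlap the antisense gene Gm26714.

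Bipolar cell and Mueller glia markers were low at day 4 as well. Of 10 bipolar cell genes, Cabp5, a calcium-binding protein, and Pcp2 fell, by 4.50 and 3.87 (limma, adjusted p = 0.0373 in 4 of 4 libraries and 0.0234 in 3 of 4), and 4 fell adjusted over the list alone. The median was −1.73 over the list, with −2.55 and −1.41 within the batches (camera, adjusted p = 8.39e-06, and adjusted p = 0.0578 with an estimated correlation). For Pcp2, 51.5% of the exon bases overlap Pet100 on the opposite strand. Of 12 Mueller glia and astrocyte genes, 1 fell, the glutamine synthetase gene Glul, and 6 adjusted over the list alone. The median was −1.95 over the list, with −3.97 and −0.23 within the batches (camera, adjusted p = 0.000143, and adjusted p = 0.342 with an estimated correlation). Of 16 rod genes none was called (median of −0.50, with −1.05 and −0.10 within the batches; camera, adjusted p = 0.00135, and adjusted p = 0.56 with an estimated correlation), and Gnat1 had −0.66 (limma, adjusted p = 0.288). None of 8 cone genes (median of −0.34, with −2.73 and 0.83 within the batches; camera, adjusted p = 0.526) and none of 7 retinal ganglion cell genes (−0.53, adjusted p = 0.179) was called, and 0 of either adjusted over the list alone. Of the other cell lists, 4 amacrine and horizontal cell genes had a median of −0.70 (1 lower adjusted over the list alone), 3 endothelial and pericyte genes −1.88, with −4.49 and 0.10 within the batches, 2 neutrophil genes 0.07 and 1 lymphocyte gene 1.18, with none called, and no erythrocyte gene passed the filter. Of 5 monocyte genes, Ms4a4c rose by 2.43 (limma, adjusted p = 0.0309, 2 of 4 libraries above all of day 0; 1 adjusted over the list alone; median of 0.34; camera, adjusted p = 0.396). Of 9 border-associated macrophage genes, Lyve1, a hyaluronan receptor, fell (1 adjusted over the list alone), and the list's median of 0.86 and mean of 0.26 differed in sign from its test, which pointed down (camera, adjusted p = 0.804).

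Of the 684 higher genes at day 4, 380 were protein coding and 257 were pseudogenes. The split depended on the scaling. The median of all genes was 0.16 as deposited, −0.16 with median-of-ratios factors and 0.02 with quantile normalisation, and the calls were 158 higher and 119 lower with the factors (57% higher against 86.6%) and 258 higher and 118 lower with quantile normalisation (68.6%). The count was 393, 267 and 499 without day 4 replicates 1, 2 and 3. Of the 53 genes called under the naming rule, 37 kept the call in all 16 fits that left out a library, and 16 did not (among them Mcm5, Cabp5, Myl12a, Fcrls, Bcl2a1b, Ifitm3, C5ar1, Psme1, Atp6v0c, Cox5a, Sdhb, Rps2, Rpl27, Pcp2 and Ms4a4c), with a highest adjusted p of 0.127. The fits without day 0 replicates 1 to 4 lost 6, 5, 3 and 5 of them, those without day 4 replicates 7, 16, 8 and 4, and each of the others at most 1. Rescaling with median-of-ratios factors ended the calls of Cfl1, Cd63, Ctsc, Fcgr1 and Rpl6. It also ended those of Atp6v0c, Bcl2a1b, C5ar1, Cabp5, Cox5a, Fcrls, Ifitm3, Ms4a4c, Myl12a, Psme1, Rpl27, Rps2 and Sdhb.

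**Figure D2:**
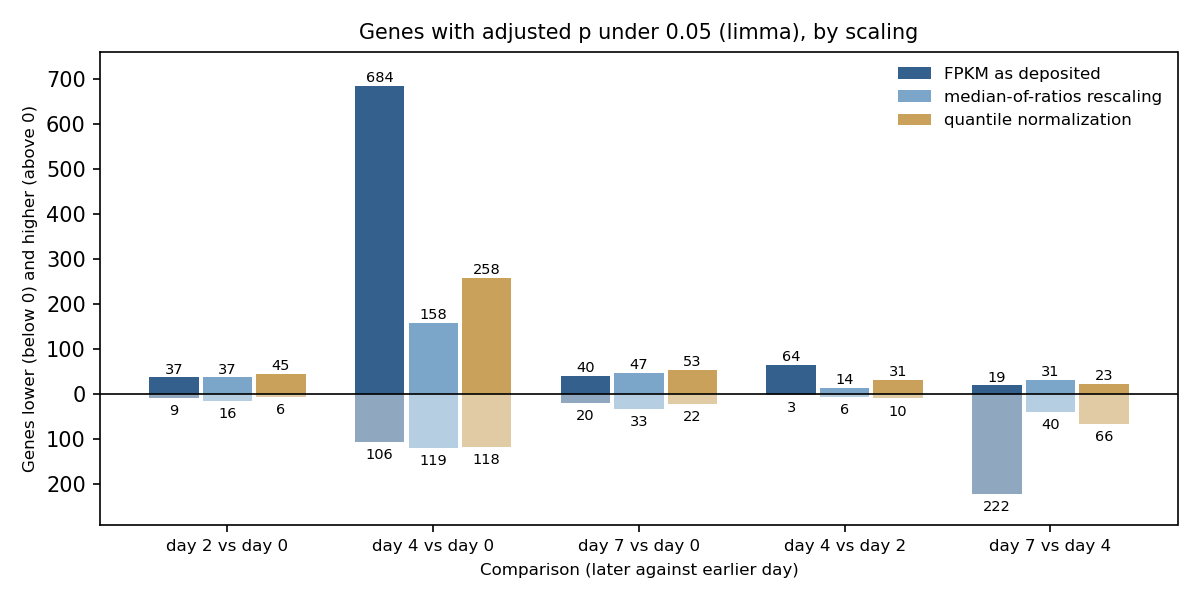
Number of genes with an adjusted p under 0.05 (limma) that were higher, drawn upward, or lower, drawn downward, in each of the 5 comparisons under the deposited values, median-of-ratios factors and quantile normalisation. At day 4 against day 0 the higher and lower genes number 684 and 106 as deposited, 158 and 119 with the factors and 258 and 118 with quantile normalisation.

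The comparison of day 7 with day 0 showed higher interferon-induced genes at the later day. Ifi27l2a rose from 197 ± 95.8 to 2356 ± 1263 FPKM (SD, n = 4), by 3.64 ± 0.49 (limma, adjusted p = 0.00578; 3.67 and 3.6 within batches 1 and 2). Ifi211 and Ifi204, members of the Ifi200 family of DNA sensors, rose by 3.58 ± 0.46 and 3.21 ± 0.43 (adjusted p = 0.00517 for both), and Ifitm3, which blocks virus entry, and Slfn2 rose by 2.44 ± 0.32 and 5.21 ± 0.66 (adjusted p = 0.00517 for both). Ifit1, an inhibitor of viral translation, had 4.79 (adjusted p = 0.0293). Cxcl13, a chemokine that attracts B cells, was listed at 0 in all day 0 libraries and was at 91.0 ± 44.4 FPKM at day 7 (adjusted p = 0.00177). All of these were higher in 4 of 4 libraries.

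In all, 60 genes changed (limma), 40 higher and 20 lower. Of 29 interferon genes, 7 rose over all genes tested and 18 adjusted over the list alone. The median was 2.21 over the list, with 1.95 and 2.24 within the batches (camera, adjusted p = 1.18e-21, and adjusted p = 0.00394 with an estimated correlation). Of 28 disease-associated microglia genes, 5 rose over all genes tested, with 17 higher and 1 lower adjusted over the list alone. The median was 1.28 over the list, with 1.52 and 0.81 within the batches (camera, adjusted p = 1.46e-15, and adjusted p = 0.0263 with an estimated correlation). Among the 5 were Cd63 (1.67, limma, adjusted p = 0.00769), the lectin receptor Clec7a (2.31, adjusted p = 0.0223) and Cd52 (2.02, adjusted p = 0.0298), in 4 of 4 libraries each. Of 17 cytokine genes, 4 rose over all genes tested and 11 adjusted over the list alone. The median was 2.32 over the list, with 2.78 and 2.31 within the batches (camera, adjusted p = 9.21e-15, and adjusted p = 0.000715 with an estimated correlation). The 4 were Cxcl13 and Ccl12, Ccl4 and Ccl3 (2.59, 3.76 and 2.93, limma, adjusted p = 0.0223, 0.0273 and 0.0488, 4 of 4 each).

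Of 5 monocyte genes, Ms4a4c and Plac8 rose, by 5.24 ± 0.60 and 3.14 ± 0.58 (limma, adjusted p = 0.00258 and 0.031, 4 of 4 libraries each; 2 adjusted over the list alone). The list median was 0.91 (0.48 and 1.53 within the batches; camera, adjusted p = 0.000648, and adjusted p = 0.0497 with an estimated correlation). The class I gene H2-Q7, 1 of 16 in its list, had 2.24 (limma, adjusted p = 0.0442; 8 adjusted over the list alone; median of 0.93; camera, adjusted p = 1.95e-06, and adjusted p = 0.172 with an estimated correlation). Of 40 cell cycle genes, Ccnb2 and Birc5 had 4.12 and 3.30 (limma, adjusted p = 0.0405 and 0.0488; 3 adjusted over the list alone; median of 0.94; camera, adjusted p = 3.5e-07, and adjusted p = 0.365 with an estimated correlation). The Fc receptor Fcgr1 had 1.89 (limma, adjusted p = 0.0369), the only called member of the phagocytosis list (3 adjusted over the list alone; median of 0.51; camera, adjusted p = 2.28e-05, and adjusted p = 0.365 with an estimated correlation). Of the homeostatic list none was called and 2 fell adjusted over the list alone. The median was −0.76 over the list, with −0.08 and −1.27 within the batches (camera, adjusted p = 0.00025, and adjusted p = 0.457 with an estimated correlation). Of 17 glycolysis genes none was called and 0 adjusted over the list alone. The median was −0.46 over the list, with −1.02 and 0.00 within the batches (camera, adjusted p = 0.00259, and adjusted p = 0.457 with an estimated correlation). Of 30 oxidative phosphorylation genes none was called and 4 rose adjusted over the list alone. The median was 0.56 over the list, with 0.15 and 0.74 within the batches (camera, adjusted p = 3.43e-07, and adjusted p = 0.233 with an estimated correlation).

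Lower at day 7 were Cend1 (−4.09, limma, adjusted p = 0.013), Zdhhc14 (−3.53, adjusted p = 0.0105), the fatty acid desaturase Fads1 (−3.90, adjusted p = 0.0264) and Syn1 (−3.41, adjusted p = 0.0449). So were Lyve1 (−2.95, adjusted p = 0.0293), the purine synthesis enzyme Gart (−2.66, adjusted p = 0.0488) and Tmem150a (−2.60, adjusted p = 0.0369), in 4 of 4 libraries each. Of the exon bases of Gart, 19.7% overlap the antisense gene Gm15964. Ctu1 was listed at 0 in all day 7 libraries (adjusted p = 0.0243). The lists of other retinal cells had medians of −0.94 for bipolar cells, −0.55 for Mueller glia and 0.29 for rods (camera, adjusted p = 0.109, 0.472 and 0.132, and 0 adjusted over the list alone for each). The medians were −1.01 for cone and −0.68 for retinal ganglion cell genes (camera, adjusted p = 0.213 and 0.248), and −1.32 for 3 endothelial and pericyte genes, −0.32 for 4 amacrine and horizontal cell genes, −0.35 for 2 neutrophil genes and 2.22 for 1 lymphocyte gene, which were too few to test. Of 9 border-associated macrophage genes, 1 fell, Lyve1, and 1 adjusted over the list alone. The median was −0.75 over the list, with −0.90 and −0.47 within the batches (camera, adjusted p = 0.0498, and adjusted p = 0.249 with an estimated correlation). Within batches 1 and 2 the rod median was −0.90 and 1.38, of opposite sign. Nuclear copies of mitochondrial genes took 14.28% of the reads at day 7, against 9.18% at day 0, with overlapping libraries (9.89% to 21.97% and 5.31% to 17.81%).

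Days 0 and 7 share no 6-digit title code, so no libraries of one code compare them directly. With this code as a covariate, a setting chosen after seeing the data, 28 genes were called and 10 of them were among the 60. With the bipolar cell and Mueller glia lists as covariate, also chosen after seeing the data, 15 were called, 14 of them among the 60. With the code, Ifi27l2a and Ccl12 lost the call, and Cxcl13, Slfn2, Ifi211, Ifi204 and Ifitm3 kept it. The count at day 7 was 27 and 30 without day 0 replicates 1 and 2, and 29, 17, 24 and 16 without day 7 replicates 1 to 4. Of the 28 named genes called, Cxcl13, Ms4a4c, Slfn2, Ifi27l2a, Ifi211, Cend1, Zdhhc14, Cd63, Ifitm3 and Ifi204 kept the call in all 16 fits, and 18 lost it in at least 1, with a highest adjusted p of 0.159. The fits without day 0 replicates 1 to 4 lost 13, 13, 9 and 10 of them, those without day 2 replicates 5, 5, 7 and 6, those without day 4 replicates 6, 7, 2 and 6, and those without day 7 replicates 14, 16, 14 and 18.

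**Figure D3:**
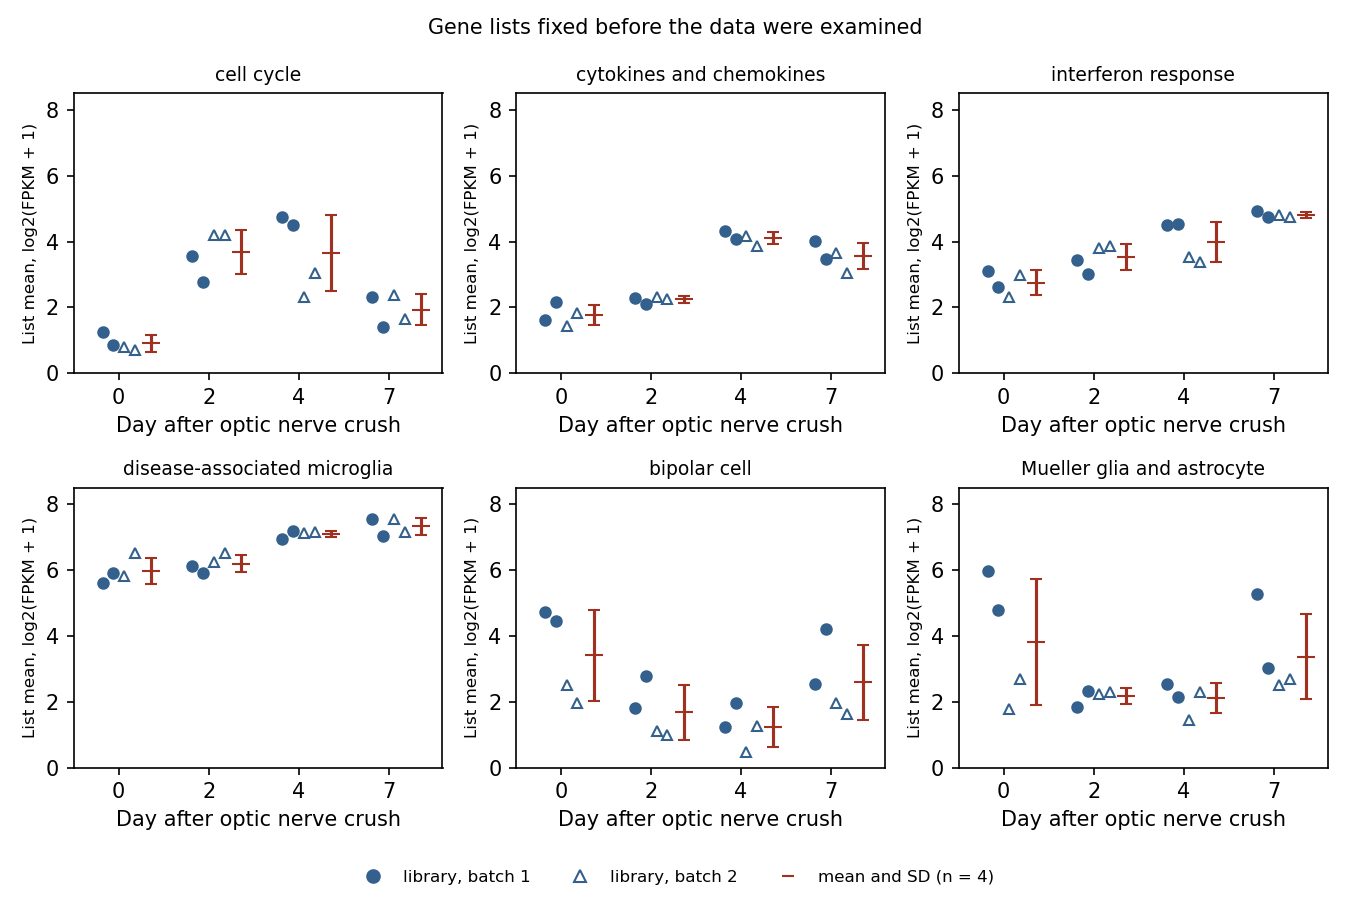
Mean log2(FPKM + 1) over the genes of a list on the vertical axis against the day on the horizontal axis, 1 panel per list and 1 point per library, the symbol giving the batch. The plotted means cover all genes of a list, tested or not. Over the tested genes only, the fitted changes against day 0 had a median of 3.47 for the cytokine list at day 4. That of the interferon list at day 7 was 2.21. These medians are not differences of the plotted means.

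The comparison of day 4 with day 2 addressed what changed between these days. Cytokine genes rose, with Ccl12 from 638 ± 252 to 8024 ± 3579 FPKM (SD, n = 4), by 3.62 ± 0.43 (limma, adjusted p = 0.00345; 3.38 and 3.86 within batches 1 and 2). Ccl4 and Ccl3 rose by 3.85 and 3.49 (adjusted p = 0.0208 for both), Tnf by 4.60 ± 0.86 (adjusted p = 0.0316; 5.32 and 3.89), Il1b by 4.79 (adjusted p = 0.0454) and Ccl2 by 4.24 (adjusted p = 0.0438). Nolc1, a nucleolar protein, and the immediate early gene Ier2 rose by 4.18 ± 0.67 and 3.43 ± 0.58 (adjusted p = 0.0153 and 0.0208). Ier2 was the only called member of 22 immediate early and dissociation genes, a list that holds genes known to respond to the handling of cells. In this list 4 rose adjusted over the list alone and 20 had a positive change. The median was 1.04 over the list, with 1.56 and 0.76 within the batches (camera, adjusted p = 9.9e-05, and adjusted p = 0.365 with an estimated correlation). The glycolytic enzymes Ldha and Tpi1 rose by 1.40 and 1.37 (limma, adjusted p = 0.0291 and 0.0409), the called members of 17 glycolysis genes, with 3 higher adjusted over the list alone. The list median was 0.54, with 0.47 and 0.64 within the batches and 0.24 with median-of-ratios factors (camera, adjusted p = 0.00278, and adjusted p = 0.459 with an estimated correlation). Atp6v0c, Cd63 and Lpl rose by 1.18, 1.30 and 3.66 (limma, adjusted p = 0.0208, 0.0271 and 0.0438). The mitotic phosphatase Cdc25c and Ypel3 fell, by 2.64 and 2.19 (adjusted p = 0.0208 and 0.019). Of the exon bases of Cdc25c, 12.7% overlap Gm3550 on the opposite strand. Each named gene moved in its direction in 4 of 4 libraries.

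Between days 2 and 4, 67 genes changed (limma), 64 higher and 3 lower. Of 17 cytokine genes, 6 rose over all genes tested and 11 adjusted over the list alone. The median was 2.89 over the list, with 2.47 and 1.59 within the batches (camera, adjusted p = 4.31e-12, and adjusted p = 0.000952 with an estimated correlation). Of 40 cell cycle genes none was called. The median was −0.32 over the list, with 1.27 and −1.40 within the batches, of opposite sign (camera, adjusted p = 0.0988; 0 adjusted over the list alone). Bipolar cell, Mueller glia and rod lists had medians of −0.25, 0.01 and −0.33 (camera, adjusted p = 0.218, 0.362 and 0.0149, the last with adjusted p = 0.615 with an estimated correlation); that of Mueller glia was −0.11 with median-of-ratios factors.

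The median of all genes moved from 0.16 to −0.05 with those factors, and the calls were then 14 higher and 6 lower (70% higher against 95.5%), and 31 and 10 with quantile normalisation (75.6%). The day 4 against day 2 count was 25, 28, 2 and 3 without day 2 replicates 1 to 4, 31, 2, 11 and 2 without day 4 replicates 1 to 4, and 104 without day 7 replicate 4. Days 2 and 4 share no 6-digit title code, so no libraries of one code compare them directly. With this code as a covariate, chosen after seeing the data, 0 genes were called, so that Ccl12 lost its call too (limma, 1509 at an unadjusted p under 0.05). Of the 15 named genes called without it, Ccl12 alone kept the call in all 16 fits, and the highest adjusted p of the other 14 was 0.15. The fits without day 0 replicates 1 to 4 lost 3, 3, 2 and 1 of them, those without day 2 replicates 10, 9, 14 and 14, those without day 4 replicates 7, 14, 13 and 14, and those without day 7 replicates 3, 4, 3 and 0.

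The comparison of day 7 with day 4 showed mostly lower levels at the later day. Pold2, a subunit of DNA polymerase delta, changed by −4.70 ± 0.91 (limma, adjusted p = 0.0192), the helicase genes Mcm7 and Mcm6 by −4.09 and −4.01 (adjusted p = 0.0226 and 0.0358) and Uhrf1, which maintains DNA methylation, by −3.61 (adjusted p = 0.0432). Nusap1 changed by −3.30 ± 0.56 (adjusted p = 0.0095), the serine synthesis enzyme Psat1 by −4.09 (adjusted p = 0.0324) and Polr3d, a subunit of RNA polymerase III, by −3.67 (adjusted p = 0.0386). Ccl12 fell from 8024 ± 3579 to 1634 ± 704 FPKM (SD, n = 4; −2.27 ± 0.43, adjusted p = 0.0169), and Ldha, Atp5g1 and the chaperone Hspa8 changed by −1.17, −1.09 and −1.22 (adjusted p = 0.0349, 0.0413 and 0.0204). All were lower in 4 of 4 libraries.

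Higher at day 7 than at day 4 were Cxcl13 (4.58 ± 0.67, limma, adjusted p = 0.00504; 3.34 and 5.82 within the batches), Car8 (4.67 ± 0.70, adjusted p = 0.00579), Gpm6a (4.58 ± 0.51, adjusted p = 0.00117), Pcp2 (4.53, adjusted p = 0.0226), the lectin receptor Clec4a3 (3.82, adjusted p = 0.0272) and Ms4a4c (2.80, adjusted p = 0.0324), in 4 of 4 libraries each. Gpm6a and Pcp2 are neuronal genes, and the bipolar cell, Mueller glia and rod lists had medians of 0.83 (1.27 and 0.29 within the batches), 1.14 (1.99 and 0.53) and 0.91 (0.12 and 1.55), with camera adjusted p = 0.000427, 0.000112 and 1.4e-07. These became adjusted p = 0.162, 0.341 and 0.342 with an estimated correlation, with 2, 1 and 0 members higher adjusted over the list alone. Nuclear copies of mitochondrial genes took 14.28% of the reads at day 7 and 5.48% at day 4.

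In all, 241 genes changed between days 4 and 7 (limma), 19 higher and 222 lower. Of 40 cell cycle genes, 5 fell over all genes tested and 14 adjusted over the list alone. The median was −1.43 over the list, with −2.66 and −0.31 within the batches (camera, adjusted p = 3.5e-07, and adjusted p = 0.365 with an estimated correlation). No interferon gene was called. The median was 0.87 over the list (camera, adjusted p = 3.23e-07, and adjusted p = 0.0917 with an estimated correlation; 0 adjusted over the list alone). The ribosomal protein and oxidative phosphorylation lists had medians of −0.41 and −0.32, which were 0.05 and 0.13 with median-of-ratios factors (camera, adjusted p = 0.00119 and 0.315, the first with adjusted p = 0.638 with an estimated correlation; 5 and 3 lower adjusted over the list alone). Ldha was the only called member of 17 glycolysis genes (2 lower adjusted over the list alone). The list median was −0.51, and −0.09 with median-of-ratios factors (camera, adjusted p = 0.0309, and adjusted p = 0.592 with an estimated correlation). The median of all genes moved from −0.26 to 0.05 with the factors, and the calls were 31 higher and 40 lower (43.7% higher against 7.9%), and 23 and 66 with quantile normalisation (25.8%).

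With the bipolar cell and Mueller glia lists as covariate the day 7 against day 4 count was 46, with 35 of them among the 241, and with the full 6-digit title code it was 104, with 59, both chosen after seeing the data. With neither, the count was 84, 62, 157 and 117 without day 4 replicates 1 to 4 and 81 without day 7 replicate 2. Of the 17 named genes called, Car8, Cxcl13, Gpm6a and Nusap1 kept the call in all 16 fits and 13 lost it in at least 1, with a highest adjusted p of 0.153. The fits without day 4 replicates 1 to 4 lost 11, 12, 7 and 11 of them, those without day 7 replicates 5, 12, 6 and 10, those without day 0 replicates 1, 2, 1 and 2, and those without day 2 replicates 1, 1, 2 and 0.

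Over the 4 days together, 427 genes differed (limma F test), and 58, of which 53 among the 427, with the bipolar cell and Mueller glia lists as covariate. The count was 267 without day 0 replicate 2, 181, 149, 266 and 259 without day 4 replicates 1 to 4, and 266 without day 7 replicate 2. The changes of all genes within the 2 batches were weakly correlated across genes, with 0.096 and 0.279 for days 2 and 4 against day 0, 0.15 for day 7, 0.039 for day 4 against day 2 and 0.234 for day 7 against day 4, where genes are not independent replicates. A change that differed between the batches was found for 15 genes (limma interaction test), and for 0 of the 161 named genes tested, with a lowest adjusted p of 0.127 among them and 1618 genes at an unadjusted p under 0.05 overall.

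Calls against day 0 were shared between days. Days 2 and 4 shared 32 higher and 7 lower genes, where independent lists of these sizes would share 1.71 and 0.0645. Days 4 and 7 shared 32 higher and 12 lower (1.85 and 0.143), and days 2 and 7 shared 5 higher and 3 lower (0.1 and 0.0122). The comparisons use the same day 0 libraries. In 100 simulations of unchanged groups against shared controls no call was shared, but the adjustment keeps calls in unchanged groups rare, so this value does not bound the part that the shared libraries add. With day 0 split so that each comparison used other control libraries, fewer genes were called. Days 2 and 4 then shared 4 of the 6 genes higher and 0 of the 6 genes lower at day 2. Days 4 and 7 shared 4 of the 10 genes higher and 1 of the 2 genes lower at day 7, and days 2 and 7 shared none of these. The covariance of the changes across genes was 0.557, 0.501 and 0.421 for these pairs of days, in the same order, against 0.273, 0.268 and 0.256 in the simulations. The correlation was 0.628, 0.54 and 0.545, against 0.49, 0.475 and 0.466 in the simulations, and 0.264, 0.178 and 0.145 with split controls.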

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

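Of the tests in this part, the comparison with the rod list, the fits with the rod list or with the bipolar and Mueller lists as covariate, and the count of Y-linked reads were chosen only after the result was seen.

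In 29 of 267 groups of 4 libraries, a single library lay apart from the others, with a gap to the nearest one above Dixon's 95% limit for 4 values when divided by the group's range. For normally distributed values the limit is passed in about 1 in 20 groups, or 13.3 here. Many groups were of called genes with values at or near 0, which are not so distributed, so 13.3 does not measure chance. Of the 29, 10 were at day 0, but the days differed in their number of groups, so this does not single out day 0. In several groups a single library held a low value and the others were listed at 0, so that the gap made up the whole range (1.0). These were Ccnb2 (0.193 FPKM) and Spc24 (0.0382) in day 0 replicate 2, Cabp5 (0.0397) in day 4 replicate 2, Car8 (0.0444) and Id3 (0.0239) in day 4 replicate 1, Tcim (0.0353) in day 4 replicate 4 and Polr3d (0.0248) in day 7 replicate 3. Higher values against 0 in the others were Arxes2 in day 4 replicate 2 (6.65 FPKM), Cxcl10 in day 0 replicate 2 (17.9) and Ifit1 in day 0 replicate 1 (11.3). The mean log2 value of the erythrocyte list was 0.191 in day 4 replicate 3 and 0 in the other day 4 libraries (1.0), and 0.438 in day 7 replicate 2 (gap of 0.943).

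Day 0 replicate 1 was higher than the other day 0 libraries for Birc5 (0.46 FPKM, gap of 0.941), Mcm5 (1.83 FPKM, 0.955) and Tyms (1.7 FPKM, 0.952), and lower for Ccl12 (65.6 FPKM against 350.3 to 432.5, 0.888) and Cd52 (78.6 FPKM against 310.8 to 409.1, 0.833). Day 0 replicate 4 was higher for Ms4a4c (8.11 FPKM, 0.975). At day 2, replicate 2 was higher for Aatk (0.0874 FPKM, 0.941) and Il1b (6.89 FPKM, 0.972), and replicate 4 for Tnf (6.09 FPKM, 0.923). At day 4, replicate 1 was lower for Psme1 (177.6 FPKM against 237 to 249.9, 0.845) and Rpl27 (62.8 FPKM against 97.9 to 99.1, 0.972), and replicate 3 for Mcm6 (7.46 FPKM against 58.2 to 69.1, 0.92). At day 7, replicate 1 was higher for Pold2 (7.45 FPKM, 0.849), Psat1 (9.77 FPKM, 0.84) and Syn1 (2.2 FPKM, 0.947) and lower for Fcgr1 (77.6 FPKM against 135.3 to 150.5, 0.839), and replicate 3 had 14127982 reads against 9673372 to 9852107 (0.96).

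The 106 genes lower at day 4 than at day 0 included neuronal genes, with a median change of −2.43 (quartiles of −2.92 and −1.87). For more whole-retina RNA at day 0, the rod list had a median of −0.50 (quartiles of −0.87 and −0.27), with −1.05 and −0.10 within the batches. With the rod list as covariate the median of the 106 genes was −2.39 and 62 were still called. These values go against whole-retina RNA only if it was the sole source of rod RNA. Rod genes were abundant in the libraries of every day, so these tests cannot decide. Without day 0 replicate 1 the median was −2.29, with 47 of the 106 genes still called from fewer libraries. For these genes the fall thus did not rest on this library alone. They were picked in a fit with this library, which favours genes low against all day 0 libraries. The test therefore cannot exclude that the library added to the calls. RNA of bipolar cells and Mueller glia stays open, since with their lists as covariate the median was −2.17 but the median SE rose from 0.56 to 0.87 and 4 genes were still called, and within batch 2 the lists had −1.41 and −0.23 against −2.25 for the 106 genes. A change in the microglia after the injury, or with the age of the mice, may also be the source and was not tested.

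The genes higher at day 4 included 257 pseudogenes, and 256 of them had a tested parent gene at 90% identity or more. For 99.6% of these the parent rose by at least 50% of the pseudogene's own log2 change. The parent was itself called for 84.8%, against 9.4% for 2281 other pseudogenes, and the median changes were 1.42 for the pseudogenes and 1.39 for their parents, of which 115 were distinct. Reads shared with the parents may therefore account for these calls, and the count of 684 higher genes is then not one of independent genes. Transcription of the pseudogenes themselves was not tested.

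The titles of day 2 replicates 3 and 4 begin with F where the others begin with M, and without both libraries the day 2 count was 1. Female mice are argued against, since the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 1252 and 1036 reads in these libraries and Xist had 2 and 0. What the prefix stands for is not given in the sources used here, and no biological explanation was tested.

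Other splits of the same libraries into groups of 4 gave fewer genes than the real split, which was the 1 of 35 with as many genes in each comparison. The real split gave 46 genes and the highest other 8 at day 2 against day 0, 790 and 3 at day 4, 60 and 17 at day 7, 67 and 3 for day 4 against day 2, and 241 and 2 for day 7 against day 4. Over the 4 days the real split gave 427 genes and the highest other 84, and it was 1 of 100 splits drawn. No other split that was tried reached the real count, but 1 of 35 is the smallest share that 4 libraries against 4 allow. The other splits also mix libraries of different days, which widens the spread within their groups and lowers their counts. Chance can therefore not be excluded by these splits. As the labels do not say that the libraries came from separate animals, this does not exclude chance differences between animals.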

How the results depend on the processing

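The 7 alternatives named in the methods as chosen after seeing the data were the only tests here chosen after the result was seen. All alternatives were run, 36 settings in all. Over named genes, 15745 results were called in both fits or in neither, 1383 lost the call and 77 gained it. None reversed while called (705 changed sign where called in neither). List results stayed in 504 cases, lost the call in 91 and gained it in 5. Most results that stayed, of genes and of lists, were called in neither fit, so these totals overstate how often a call held. Of the 131 calls of named genes, single settings kept from 0 (batch 2 alone) to 125 (pseudocount of 5). Of the counts, 110 stayed within 1.5 times and 110 moved further. Counts below are called genes, with those shared with the reported calls in brackets, and the cause of a move was not tested unless fewer genes or libraries entered. The comparisons are day 2, day 4 and day 7 against day 0, day 4 against day 2 and day 7 against day 4, and the F test. Depth limits low genes, since a value of 0 in a gene of 1 kb allows up to 0.191 to 0.347 FPKM.

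With no filter the counts were 14 [14], 308 [306], 13 [13], 2 [2], 63 [63] and 120 [119], where more genes were tested. With protein-coding genes only, and so fewer genes, they were 23 [22], 325 [323], 36 [33], 29 [28], 95 [94] and 239 [223]. A mean of at least 5 FPKM gave 133 [62] for day 4 against day 2, 380 [221] for day 7 against day 4 and 669 [382] for the F test. A pseudocount of 0.1 gave 38 [38] at day 7 and 1 of 5 gave 148 [66] for day 4 against day 2.

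Median-of-ratios factors gave 277 [237] at day 4, 20 [17] for day 4 against day 2, 71 [54] for day 7 against day 4 and 222 [195] for the F test, and quantile normalisation gave 376 [328], 41 [30], 89 [78] and 279 [224] for the same. Library weights gave 1488 [776], 204 [66], 939 [241] and 1114 [425]. Limma voom gave 491 [414] at day 4, 24 [21] at day 7, 147 [111] for day 7 against day 4 and 258 for the F test. Rescaling without nuclear copies of mitochondrial genes gave 33 [32] for day 4 against day 2 and 122 [122] for day 7 against day 4. Without the batch term 39 [39] were called at day 7.

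Only the groups compared, with fewer libraries, gave 401 [359] at day 4, 2 [2] at day 7, 32 [22] for day 4 against day 2 and 6 [6] for day 7 against day 4. Batch 1 alone gave 20 [11], 303 [183], 2 [1], 1 [0], 0 and 30 [21], and batch 2 alone gave 0 for all 6 (limma), with 1053, 1748, 1514, 1428, 1378 and 1788 genes at an unadjusted p under 0.05. The 0 for day 7 against day 4 in batch 1 had 2447 such genes. The limma fit with an interaction of day and batch, which uses both batches together, also called genes within each batch. For the comparisons in the same order, without the F test, these were 71, 410, 12, 3 and 73 within batch 1. Within batch 2 they were 61, 195, 162, 67 and 91. The 0 with batch 2 alone, where fewer libraries entered, thus does not show an absence of change there. Without the libraries of prefix F the count was 1 [0] at day 2 and 0 for day 4 against day 2 (limma, 1537 at an unadjusted p under 0.05). Without day 0 replicate 1 and day 7 replicate 4 it was 17 [13] at day 7 and 152 [67] for day 4 against day 2. With single libraries left out the counts ranged from 8 to 77, 267 to 955, 16 to 57, 2 to 104, 62 to 256 and 149 to 510.

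The full 6-digit code as covariate gave 126 [40], 379 [275], 28 [10], 0 (limma, 1509 at an unadjusted p under 0.05) and 104 [59]. The rod list as covariate gave 38 [36] at day 7 and 74 [65] for day 7 against day 4. The bipolar and Mueller lists gave 0 at day 2 (limma, 1105 at an unadjusted p under 0.05), 37 [28] at day 4, 15 [14] at day 7, 46 [35] for day 7 against day 4 and 58 [53] for the F test.

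The replicate number as a block gave 30 [29] at day 2, 22 [21] at day 7, 31 [29] for day 4 against day 2, 152 [149] for day 7 against day 4 and 245 [235] for the F test. The numbers do not pair the libraries: of 24 pairs with the same number, 5 had a correlation of deviations above 0.1 (range of −0.056 to 0.234, median of 0.04, against 0.048 for other numbers of the same batch), and 5 of 16 libraries correlated best with their own number.

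At day 4 Il1a had 5.97 in batch 1 alone, 5.16 in batch 2 alone, 7.48 with voom and 6.22 with the bipolar and Mueller lists (adjusted p = 0.0761, 0.316, 0.0636 and 0.185, limma), Tnf had 5.30 in batch 2 alone and 5.89 with those lists (0.32 and 0.101), and Gpr84 1.75 and 1.54 (0.282 and 0.325). With single libraries left out the ranges were 2.08 to 2.71 for Gpr84, 5.21 to 5.56 for Tnf and 4.62 to 6.59 for Il1a. Of the 55 list calls, 7 held with an estimated correlation and 22 were called by fry, 21 of them shared.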

Other observations

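The gene families and clock genes of this part were chosen, and looked at, only after the gene results were seen. A list test on them would use the data that picked them, so only the called genes (limma, over all genes tested) and the medians are given. At day 4 against day 0, 19 of 38 proteasome subunits rose (median of 1.20, and 0.73 with median-of-ratios factors). Of the 8 subunits of the chaperonin CCT, which folds actin and tubulin, Cct3, Cct5, Cct8 and Tcp1 rose (median of 1.6, and 1.14 rescaled). Of 46 nucleolar and ribosome biogenesis factors, 10 rose, among them Ncl, Npm1, Fbl and Nop56 (1.47 and 1.06), and of 55 translation initiation factors 7 rose (0.97 and 0.52). Of 20 genes of protein folding in the endoplasmic reticulum 5 rose (0.68 and 0.22), and of 19 aminoacyl-tRNA synthetases none was called (1.15 and 0.70).

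At day 7 against day 4, 4 CCT genes, 5 proteasome genes, 5 initiation factors, 5 nucleolar factors and 6 folding genes fell. The medians were −1.53, −0.81, −0.79, −1.33 and −1.29, and −1.07, −0.36, −0.37, −0.98 and −0.89 with median-of-ratios factors. At day 7 against day 0, of 21 genes of the Schlafen, Ifi200 and Phf11 families, which interferon induces in part, Ifi204, Ifi211, Ifi205, Slfn2, Phf11a and Phf11b rose (median of 1.44, and 1.45 rescaled). Of 14 genes of the circadian clock, Nr1d1, Arntl and Dbp fell at day 4 against day 0, by 3.30, 2.92 and 2.79 (limma, adjusted p = 0.0165, 0.0327 and 0.0344; 3, 4 and 4 of 4 libraries below all of day 0), and Ciart had −2.75 (adjusted p = 0.0565). At day 0, Nr1d1 was at 57.9, 39.2, 12.2 and 1.51 FPKM and Dbp at 29.6, 23.3, 7.13 and 8.23 FPKM in replicates 1 to 4. Arntl was at 14.15, 5.55, 8.27 and 6.6 FPKM and so lowest in replicate 2. The mean log2 value of the bipolar cell list was 4.73, 4.46, 2.51 and 1.96 in the same libraries. The bipolar cell and Mueller glia lists had medians of −1.73 and −1.95 in this comparison. These 4 clock genes were not recomputed under the other settings. The time of day at which the cells were taken is not given in the sources used here.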
